A study of Homo sapiens with 155 samples.

How the data were processed

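Gene expression was measured in freshly brushed human bronchial epithelial cells with 1-colour Agilent arrays, each labelled as a biological replicate. There were 27 controls, 72 with asthma that was not severe and 56 with severe asthma, grouped per the labels. Per the labels' protocols the brushings were mostly epithelial cells and RNA of checked quality was amplified and labelled with Cy3. The deposited scanner files hold intensity values (processed signal, median signal, background median) extracted per the file headers, with Agilent Feature Extraction 10.7.3.1 named in the submitters' processing notes, and flags per spot. The authors also deposited normalized log2 values of 30889 probes, made by cyclic loess per the series text. These values had a median correlation of 0.997 with the log2 median signal of the same array and a slope of 0.988, with column medians from 7.847 to 7.99, and were used as an alternative only. The labels name a different array design from the file headers, so gene names were taken only from the RefSeq accessions in the files, matched without version to the supplied RefSeq genes. Of 41000 probes, 26309 matched 1 gene, 14615 matched none and 76 had accessions in the 2 design versions (42 and 113 arrays) that pointed to different genes, which left 17743 genes. Because the headers name different genome builds, no coordinates are given. No probe for a Y-linked gene, XIST or TSIX was kept (65 probes).

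Processed signal was floored at 1, log2-transformed, set to missing at spots marked as outliers, averaged over replicate spots and normalized by cyclic loess in 3 iterations with limma 3.58.1 (R 4.3.3, with the R package data.table at version 1.17.8). Probes well above background on at least 27 arrays were kept, and each gene was read by the 1 probe with the highest mean, which gave 15633 genes. A linear model with the 3 groups was fitted with empirical Bayes variances, and 3 contrasts and an F-test were adjusted by Benjamini-Hochberg at 0.05, with a second count at 1.5-fold. Standard errors are the moderated ones. Named genes followed a rule fixed from the design: the 10 largest rises and 10 largest falls past the threshold with a symbol, up to 4 members of each list with the smallest p past the threshold, and a preset list of known asthma, epithelial and glucocorticoid genes (POSTN, CLCA1, SERPINB2, CST1, CCL26, NOS2, CDH26, ALOX15, MUC5AC, MUC5B, SCGB1A1, FOXJ1, KRT5, CPA3, TPSAB1, CLC, FKBP5, TSC22D3, ORMDL3, GSDMB, IL1RL1, FOS and HSPA1A), of which MUC5AC and TPSAB1 had no matched probe. Some genes that met the rule are not reported here.

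Gene groups were 34 lists of 617 genes, 568 of them measured, 23 with no matched probe and 26 below the detection filter. They were tested with camera at a preset correlation of 0.01 on values in which missing ones (0.00949%) were filled with the gene's mean, adjusted over the lists and comparisons together. The same test with an estimated correlation and the rotation test fry were run beside it. Camera, the lists, the thresholds, the comparisons and most other settings were chosen before the data were examined. Chosen after seeing the data were the label permutation of list scores (100000 permutations, also within scan days), scanning campaign as a block, and fits within each of the 3 campaigns, which are runs of consecutive scan days. Settings chosen beforehand changed the normalization (75th percentile, quantile), background correction (normexp with an offset of 50), the values used, the filter, the probes per gene, the variance model, array weights, the groups in the fit, scan day, slide, the 9 doubtful arrays, cell make-up scores and the replicate number. Genes of the ciliated, squamous and leukocyte lists were still tested beside the make-up scores, which remove part of their change by construction. Normexp used the median signal, since the files hold no mean signal. An array was doubtful if its correlation with the others or its share of probes above background lay over 3 scaled MAD below the median. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

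The arrays came from 86 slides and 14 scan days, of which 39 slides and 13 days held more than 1 group, and the campaigns held 6, 14 and 7 controls, 20, 29 and 23 arrays of not severe asthma and 16, 28 and 12 of severe asthma. Campaigns differed in 10177 genes and scan days in 10836, so blocked values stand beside the results. The consensus correlation within slides was 0.227. Scan days are named only by number.

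The pipeline was tested on simulated data in which 200 of 15633 genes were changed, in 5 runs per comparison. Changes of 0.25, 0.5 and 1 in log2 were recovered in 39.4%, 75.8% and 97.9% of genes for not severe asthma against control, in 33.7%, 77.6% and 96.7% for severe asthma against control, and in 61.5%, 88.7% and 99.1% between the asthma groups. Called genes that had not been changed made up 14.9%, 13.8% and 6.18%. A moved list was found in 5 of 5 runs and an unmoved one in 0 of 5 by camera. Both lists were drawn at random and judged at an unadjusted p under 0.05. These runs therefore do not show how camera behaves on lists whose genes vary together. Of the called genes with further probes, 35 of 313, 68 of 682 and 49 of 502 had one of opposite sign, and for some genes of the report the other probe's value is given.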

Results

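RNA from freshly brushed human bronchial epithelium was hybridised to one-colour arrays, 1 per sample. There were 3 groups: 27 controls, 72 samples of asthma that the labels call not severe, and 56 samples of severe asthma. A bronchial brushing samples the surface lining of a large airway, mostly ciliated, secretory and basal cells, together with the leukocytes among them. On the median array 75.6% of probes were well above background, with a range of 41.8% to 97.5%, and the group medians were 74%, 75.7% and 75.9%. No probe was saturated. Each array correlated with the others at a median r of 0.96 across genes, no pair of arrays held identical values, and 9 arrays (1, 2 and 6 in the 3 groups) stood low in correlation or detection. The highest correlation of 2 arrays was 0.993, for arrays on 1 slide. Replicates 8 and 13 of severe asthma, on 1 slide, had near-equal macrophage scores (10.98 and 10.97) and haemoglobin scores (13.37 and 13.42). Whether any 2 arrays came from 1 person was not tested. All tests count each array as an independent sample, so a person measured more than once would count more than once. After filtering, 15633 genes were tested, and the number of arrays limits the precision of each comparison. The size of a change in a gene near background depended on how background was treated, and for some of the largest changes the value with normexp background correction is given beside it or at the end of the comparison. Values below are log2 fold changes ± standard error with Benjamini-Hochberg adjusted p from limma. For gene lists whose score passed, 3 values are given: the count of its members that passed over all genes, the same count adjusted over the list alone, and the shift of its score, the mean log2 value of its measured members. The score shift was tested by a permutation of the array labels. This test was chosen after the data had been seen, because the list test planned first, camera with a preset correlation, passed as many lists as in the real groups in 34, 7 and 15 of 100 random splits of the arrays in the 3 comparisons. None of the list calls by camera held with an estimated correlation, for which limma's camera gave 0 lists in each comparison. At an unadjusted p under 0.05 it gave 4, 3 and 2, and limma's fry gave 6, 9 and 10 adjusted.

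The first comparison asked how the bronchial epithelium in asthma that was not severe differed from that of controls. The largest rise was in CLCA1, a secreted protein of mucus-producing goblet cells that IL-13 induces (3.48 ± 0.82, adjusted p = 0.0066, or 1.95 with normexp background correction). It was well above background on 11 of 27 control and 58 of 72 asthma arrays, so the size is uncertain, and it lay above the control median in 57 of 72 arrays. Mast cell genes rose together, led by CPA3, the carboxypeptidase of mast cell granules, at 4.39-fold (2.14 ± 0.38, adjusted p = 0.000244), above the control median in 63 of 72 arrays. Genes of the IL-13 response of epithelium rose with them, and genes of the IL-17 response and of cilia were lower. In all, 859 genes passed, 450 higher and 409 lower, of which 137 changed at least 1.5-fold (77 higher and 60 lower). The share of rises depended on the processing. With 75th percentile scaling 622 of 972 genes were higher, and with normexp background correction, which also used the median signal, 350 of 829.

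Among mast cell genes, 7 of 8 measured members rose, 0 fell and 1 did not pass, and all 8 rose when adjusted over the list alone. KIT, the receptor for stem cell factor, rose by 1.15 ± 0.18 (adjusted p = 5.36e-06), MS4A2, the beta chain of the high-affinity IgE receptor, by 1.74 ± 0.35 (adjusted p = 0.00228) and SLC18A2, the vesicular monoamine transporter that loads histamine, by 1.25 ± 0.27 (adjusted p = 0.00319). TPSD1, a delta tryptase, rose by 1.55 ± 0.34. The mast cell score rose by 1.23 (permutation p = 1e-05, the smallest these permutations can give, and 0.00051 adjusted). Camera gave 4.45e-12, with adjusted p = 0.0669 with an estimated correlation. The score was above the control median in 61 of 72 arrays, and its median gene shift was 0.71, 1.44 and 0.90 within the 3 scanning campaigns. RHEX, a protein described in red cell precursors, was in no list and rose (1.93 ± 0.29, adjusted p = 5.36e-06). Other leukocyte lists gave no rise of this kind: T and NK cell genes had a median of 0.05 and macrophage genes of 0.12, with 0 of 20 and 0 of 14 members past the threshold, and B and plasma cell genes one of -0.26, with 1 of 8, MZB1, higher (0.87 ± 0.23). Neutrophil genes had a median of -0.37. Of 7 eosinophil genes 1 rose, SIGLEC8, a surface lectin of eosinophils and mast cells (0.78 ± 0.17), while CLC, the Charcot-Leyden crystal protein, was at 0.95 ± 0.42 (adjusted p = 0.166). The eosinophil score was higher by 0.328, close to the threshold (adjusted permutation p = 0.0534).

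Of 23 measured type 2 epithelial genes, those induced by IL-13, 11 rose, 0 fell and 12 did not pass (13 rose when adjusted over the list alone). POSTN, the matrix protein periostin, rose 2.75-fold (1.46 ± 0.34, adjusted p = 0.00565), NOS2, the inducible nitric oxide synthase, 2.3-fold (adjusted p = 0.02), and the protease inhibitors CST1 and FETUB by 2.16 ± 0.62 and 2.07 ± 0.55. The type 2 score rose by 0.87 (adjusted permutation p = 0.00388) and was above the control median in 60 of 72 arrays. Camera gave it 8.53e-09, with adjusted p = 0.418 with an estimated correlation. CCL26, an eosinophil-attracting chemokine, was at 1.13 ± 0.42 (adjusted p = 0.0839), SERPINB2 at 0.70 ± 0.35 (adjusted p = 0.225) and ALOX15 at 0.20 ± 0.13 (adjusted p = 0.386). IL1RL1, the IL-33 receptor, rose by 0.85 ± 0.26 but was well above background on only 1 of 27 control, 18 of 72 and 15 of 56 severe asthma arrays. CST1 and CST2 are near-identical genes that probes can share, so their values are uncertain individually.

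Goblet cell genes moved both ways. Of 17 mucin and goblet cell genes 6 rose, 1 fell and 10 did not pass (6 and 1 when adjusted over the list alone). TFF2 and TFF3, trefoil peptides secreted with mucus, rose by 0.78 ± 0.19 and 0.69 ± 0.15 (0.64 and 0.24 by the other probes of TFF3), and FOXA3, a transcription factor of goblet cells, by 0.70 ± 0.17. MUC5B, a gel-forming mucin, fell to 0.422 of the control level (-1.25 ± 0.34, adjusted p = 0.0161, or -0.93, -0.75 and -1.12 by its other probes). The list's median was 0.06 and its score rose by 0.33 (adjusted permutation p = 0.0116), with camera at 0.042 and adjusted p = 0.525 with an estimated correlation. CLCA1, TFF3, FOXA3, SPDEF and FCGBP are also in the type 2 list, and CLCA1, at 3.48, supplied much of the score's rise. The goblet and type 2 scores are therefore not separate findings. Among 20 eicosanoid genes 4 rose, 1 fell and 15 did not pass (8 and 2 when adjusted over the list alone): HPGDS, which makes prostaglandin D in mast cells, by 0.83 ± 0.21, and PTGS1, a cyclooxygenase, by 1.02 ± 0.24, while PTGES, a prostaglandin E synthase, fell by 0.69. The eicosanoid score rose by 0.20 (adjusted permutation p = 0.0151, camera 0.0153, adjusted p = 0.418 with an estimated correlation), and HPGDS is also in the mast cell list.

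Of 20 IL-17 response genes 3 fell and 17 did not pass (7 fell when adjusted over the list alone). CSF3, a neutrophil growth factor, was at 0.427 of the control level and the neutrophil-attracting chemokines CXCL6 and CXCL3 at 0.579 and 0.677. The IL-17 score fell by 0.40 (adjusted permutation p = 0.0028, camera 5.96e-06, adjusted p = 0.418 with an estimated correlation). Ciliated cell genes fell slightly: 2 of 29, HYDIN (-0.30 ± 0.08) and RFX2 (-0.21 ± 0.06), a ciliary protein and a transcription factor of ciliogenesis, passed and 27 did not (7 fell when adjusted over the list alone). The ciliated score fell by 0.15 (adjusted permutation p = 0.0116, camera 1.6e-07, adjusted p = 0.418 with an estimated correlation). FOXJ1, the master regulator of cilia, was at -0.16 ± 0.08 (adjusted p = 0.188). Oxidative phosphorylation genes rose by 0.08 in score (adjusted permutation p = 0.0282, camera 0.000153, adjusted p = 0.461 with an estimated correlation), with 2 of 27 members past the threshold and 7 adjusted over the list alone, but their median gene shift was -0.001 in the second scanning campaign. NR4A3, a nuclear receptor in the list of cyclic AMP-induced genes, fell by 1.43. Outside the lists, large falls were seen in LYPD2 (-1.35 ± 0.33), in the NADPH oxidase NOX1 (-1.08 ± 0.23, or -0.63 by its other probe) and in PTGIR, the prostacyclin receptor (-1.06 ± 0.25).

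Further lists passed camera and not the permutation test. Of 19 immediate early genes, which answer within minutes to handling and stress, 0 passed over all genes, against 10 that fell when adjusted over the list alone, with a median of -0.46 (camera 1.01e-06, adjusted permutation p = 0.056, adjusted p = 0.504 with an estimated correlation). FOS was at -0.99 ± 0.36 (adjusted p = 0.0801). Red blood cell genes had a median of -0.87, with 0 of 8 past the threshold and 3 lower over the list alone (camera 0.00968, adjusted permutation p = 0.0974, adjusted p = 0.574 with an estimated correlation), but their score passed when labels were permuted within scan days (-1.10, adjusted p = 0.0422). So did that of club cell genes (-0.25, adjusted p = 0.0455), which camera did not pass (0.232) and of which 1 of 16 fell. Neutrophil genes had a median of -0.37, with 0 of 14 past the threshold (camera 0.0247, adjusted permutation p = 0.294, adjusted p = 0.676 with an estimated correlation). The median of ribosomal protein genes, of which 1 of 28 rose, was 0.04, which turned to -0.19 after normexp background correction (camera 0.0407, adjusted permutation p = 0.258, adjusted p = 0.676 with an estimated correlation). FKBP5, a glucocorticoid receptor co-chaperone, was at 0.66 ± 0.23 (adjusted p = 0.0625), KRT5 of basal cells at 0.12 ± 0.18, and ORMDL3 and GSDMB, neighbours at a well-known asthma locus, at 0.03 ± 0.07 and -0.16 ± 0.11.

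The count of 859 depended on scanning day and cell make-up: 162 genes passed with scan day as a block and 187 with scores for ciliated, squamous and leukocyte genes as covariates, while array quality weights raised it to 1799. With scan day as a block 23 of 52 named genes kept their call, CLCA1, CPA3, KIT, RHEX and MS4A2 among them, while POSTN (1.20, adjusted p = 0.0658), NOS2 (1.13, adjusted p = 0.0785), CST1 (1.88, adjusted p = 0.106), FETUB (1.78, adjusted p = 0.0883) and MUC5B (-1.20, adjusted p = 0.0721) did not. With cell make-up scores 22 of 52 kept it. No gene passed within the first or the third campaign alone by limma, where 722 and 2478 had an unadjusted p under 0.05, and 66 passed within the second. Of 15633 genes, more than 722 would on average have such a p if none differed. The first campaign alone therefore showed no excess of small p in this comparison. With normexp background correction RHEX was at 0.72, MS4A2 at 0.74, TPSD1 at 0.45, FETUB at 0.69, NR4A3 at -0.42, NOX1 at -0.28, CST1 at 0.87 (adjusted p = 0.098) and CSF3 at -0.47 (adjusted p = 0.0777), while CPA3 was at 1.62. The count past 1.5-fold was 50 in the authors' value table and 54 with normexp background correction.

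**Figure D1:**
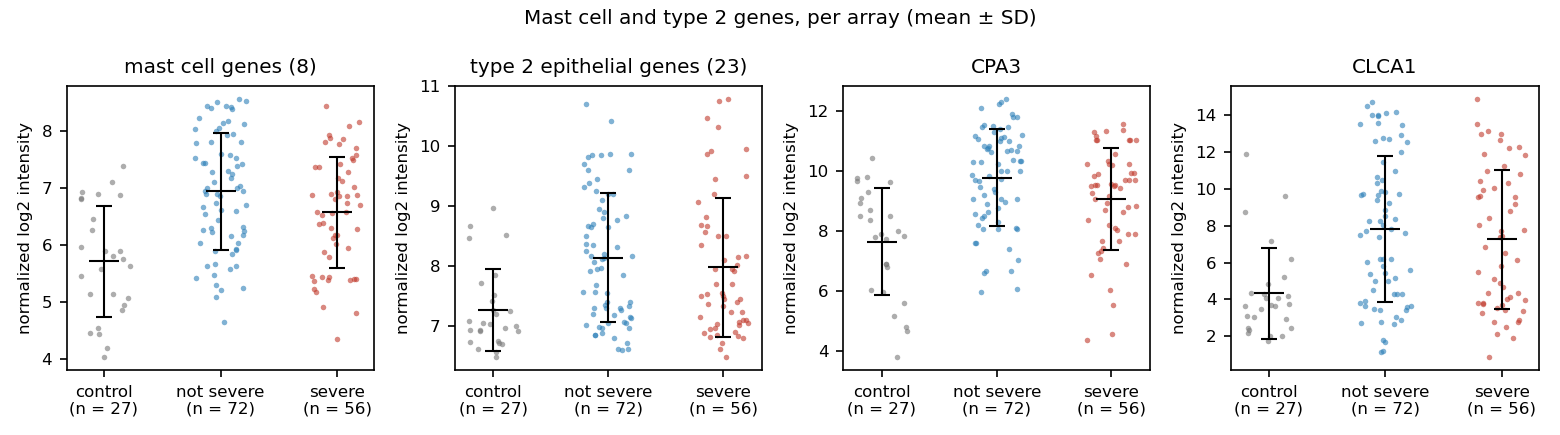
Each point is 1 array, with its normalized log2 intensity on the vertical axis and the 3 groups side by side, and bars give the mean ± SD, for the mast cell score, the type 2 score, CPA3 and CLCA1. The mean mast cell score was 5.72 in the 27 controls, 6.95 in the 72 arrays of not severe asthma and 6.58 in the 56 arrays of severe asthma, and the 3 groups overlapped widely in each panel.

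The second comparison set severe asthma against controls and gave more changes, 1871 genes (1001 higher and 870 lower), 456 of them by at least 1.5-fold (232 higher and 224 lower). CLCA1 rose by 2.92 ± 0.86 (adjusted p = 0.0126), though not past the threshold with normexp background correction (1.53, adjusted p = 0.0566). SLCO1B3, an organic anion transporter best known from the liver, rose by 2.52 ± 0.33 (adjusted p = 3.11e-08) or by 0.66 with normexp, was above the control median in 56 of 56 arrays, and was well above background on 7 of 27 control and 49 of 56 severe asthma arrays. FKBP5, which glucocorticoids induce in many tissues, rose 2.74-fold (1.45 ± 0.24, adjusted p = 3.34e-06) and SCGB1A1, the main secretory protein of club cells, fell to 0.419 of the control level (-1.26 ± 0.24, adjusted p = 4.97e-05). Mast cell, type 2, goblet cell, squamous, cell cycle and glucocorticoid-induced genes were higher, and club cell, ciliated and dendritic cell genes lower.

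Of 8 mast cell genes 4 rose and 4 did not pass (all 8 rose when adjusted over the list alone). KIT rose by 0.89 ± 0.18, CPA3 by 1.41 ± 0.39 and MS4A2 by 1.29 ± 0.37. The mast cell score rose by 0.86 (adjusted permutation p = 0.00446, camera 2.73e-05, adjusted p = 0.418 with an estimated correlation). Of 23 type 2 genes 11 rose, 0 fell and 12 did not pass (12 and 1 when adjusted over the list alone), among them POSTN at 2.51-fold, NOS2 at 2.43-fold and CST1 at 2.20 ± 0.64. The type 2 score was higher by 0.71 (adjusted permutation p = 0.0198, camera 3.9e-05, adjusted p = 0.504 with an estimated correlation). CLC passed here (1.39 ± 0.44, adjusted p = 0.0223), the only one of 7 eosinophil genes to do so (3 rose and 1 fell when adjusted over the list alone). MZB1, a chaperone of antibody-secreting cells, rose by 1.03 ± 0.24, alone among 8 B and plasma cell genes.

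Club and secretory cell genes fell in 5 of 16 cases, rose in 1 and did not pass in 10, the same counts as when adjusted over the list alone. With SCGB1A1 fell SCGB3A1, a further secretoglobin, by 1.36 and LTF, the antimicrobial lactoferrin, by 1.39, while CBR1, a carbonyl reductase, rose by 0.59 ± 0.14. The score fell by 0.33 (adjusted permutation p = 0.00446, camera 0.0174, adjusted p = 0.418 with an estimated correlation) and lay below the control median in 46 of 56 arrays. Of 17 mucin and goblet cell genes 5 rose, 1 fell and 11 did not pass (8 and 2 when adjusted over the list alone). TFF1 rose 2.27-fold and AGR2, a disulfide isomerase needed for mucin folding, 1.34-fold, while MUC5B fell to 0.427 of the control level. The goblet cell score rose by 0.35 (adjusted permutation p = 0.0052, camera 0.0153, adjusted p = 0.461 with an estimated correlation). Its list shares CLCA1, TFF3, FOXA3, SPDEF and FCGBP with the type 2 list, and CLCA1, at 2.92, supplied much of the rise. Of 29 ciliated cell genes 7 fell and 22 did not pass (11 fell when adjusted over the list alone), among them the dynein heavy chains DNAH5 (-0.50 ± 0.11) and DNAH9 (-0.29 ± 0.08) and FOXJ1 (-0.24 ± 0.08, adjusted p = 0.0283). The ciliated score fell by 0.17 (adjusted permutation p = 0.0151, camera 1.09e-06, adjusted p = 0.418 with an estimated correlation).

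Squamous cell genes rose in 4 of 19 cases and fell in 1 (the same counts adjusted over the list alone), led by KRT6A and KRT6C, near-identical keratins of stressed and squamous epithelium, at 1.98 ± 0.39 and 1.74 ± 0.38, with TGM3, an epidermal transglutaminase, lower by -0.62 ± 0.15. The squamous score rose by 0.37 (adjusted permutation p = 0.0282, camera 0.0465, adjusted p = 0.615 with an estimated correlation). Cell cycle genes rose in 9 of 21 cases, 12 when adjusted over the list alone, and none fell: BIRC5, the survival protein survivin, by 0.70 ± 0.17, and the mitotic spindle genes TPX2 and KIF20A by 0.51 ± 0.13 and 0.55 ± 0.15. Their score rose by 0.31 (adjusted permutation p = 0.0116, camera 6.07e-07, adjusted p = 0.418 with an estimated correlation). Oxidative phosphorylation genes rose slightly, 7 of 27 (8 adjusted over the list alone), with a score higher by 0.09 (adjusted permutation p = 0.00499, camera 3.9e-05, adjusted p = 0.418 with an estimated correlation).

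Of 22 glucocorticoid-induced genes 8 rose, 0 fell and 14 did not pass, over all genes and over the list alone alike. Beside FKBP5 these included MAOA, a monoamine oxidase (0.46 ± 0.08, adjusted p = 1.01e-05), DDIT4, an inhibitor of mTOR (0.59 ± 0.11), and TSC22D3, the leucine zipper GILZ (0.53 ± 0.17, adjusted p = 0.0311). The score rose by 0.27 (adjusted permutation p = 0.00391, camera 0.000877, adjusted p = 0.492 with an estimated correlation) and was above the control median in 46 of 56 arrays. Dendritic and Langerhans cell genes fell in 3 of 10 cases (5 adjusted over the list alone): FCER1A, the alpha chain of the IgE receptor, to 0.492 of the control level (-1.02 ± 0.23, adjusted p = 0.000702), CD207, langerin, to 0.535, and CCL17, a T-cell-attracting chemokine, to 0.701. That score fell by 0.49 (adjusted permutation p = 0.0028, camera 0.000153, adjusted p = 0.418 with an estimated correlation). Of 15 NRF2 genes of the oxidative stress response 1 passed, over all genes and over the list alone, AKR1B10, an aldo-keto reductase (1.34 ± 0.31). The NRF2 score rose by 0.27 (adjusted permutation p = 0.0282, camera 0.00965, adjusted p = 0.588 with an estimated correlation), which did not hold when labels were permuted within scan days (adjusted p = 0.0599).

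Outside the lists CEACAM5, a cell adhesion protein of mucosal epithelium, rose 4.41-fold (2.14 ± 0.37, adjusted p = 8e-06) and PHACTR3, a regulator of protein phosphatase and actin, by 2.26 ± 0.45. PRR4, a proline-rich secreted protein, was at 2.04 ± 0.41 by the probe used and at 0.01 by its other probe. By the probes used, the largest fall was in KCNA1, a voltage-gated potassium channel (-2.06 ± 0.34, adjusted p = 4.56e-06, or -1.73 by its other probe). It was followed by the metalloprotease MMP16 (-1.71 ± 0.28), PTGIR (-1.70 ± 0.26) and WIF1, a Wnt inhibitor (-1.61 ± 0.41, or -0.72 by its other probe). WNK4, a kinase that controls ion transport, had the strongest test among the falls (-1.53 ± 0.20, adjusted p = 1.96e-08, or -2.19 by its other probe). ANO4, at -1.47 ± 0.26, was well above background on 12 control, 14 not severe and 2 severe asthma arrays. Camera but not the permutation test passed macrophage genes (1 of 14 fell, 0 over the list alone, median -0.49, camera 0.012, adjusted permutation p = 0.23, adjusted p = 0.676 with an estimated correlation) and basal cell genes (2 of 15 rose, also over the list alone, median 0.22, camera 0.0155, adjusted permutation p = 0.067, adjusted p = 0.615 with an estimated correlation). It also passed innate antiviral and alarmin genes (4 of 18 fell, also over the list alone, median -0.15, camera 0.0247, adjusted permutation p = 0.0744, adjusted p = 0.525 with an estimated correlation) and IL-17 response genes (median -0.20, camera 0.0343, adjusted permutation p = 0.21, adjusted p = 0.615 with an estimated correlation). Of the 20 IL-17 response genes 5 fell and 15 did not pass (5 fell and 1 rose over the list alone). Among the falls were CXCL6 by 0.92 and CXCL2 by 0.57 (-0.92 by the other probe of CXCL2). Eicosanoid genes passed neither test here (score 0.10, adjusted permutation p = 0.25, camera 0.43), with 4 of 20 higher and 3 lower (5 and 4 over the list alone).

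With cell make-up scores as covariates 796 genes passed, 719 of them among the 1871, where SCGB1A1 (-0.93), FKBP5 (1.31), SLCO1B3 (2.42) and KCNA1 (-1.81) were among 58 of 96 named genes that kept their call. Those that did not included CLCA1 (2.70, adjusted p = 0.0524), POSTN (0.95, adjusted p = 0.0891) and MUC5B (-1.0, adjusted p = 0.0844). With scan day as a block 2062 genes passed, and within campaigns 9, 648 and 0, the last beside 1330 at an unadjusted p under 0.05 by limma. With normexp background correction PHACTR3 was at 1.04, FETUB at 0.69, KRT6A at 1.0, KCNA1 at -0.98, MMP16 at -0.53, WIF1 at -0.52, WNK4 at -0.65, ANO4 at -0.25 and CST1 at 0.83 (adjusted p = 0.1), while CEACAM5 was at 1.63 and PTGIR at -1.50. With it 124 genes passed 1.5-fold, against about 1.6e+02 in the authors' value table.

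**Figure D2:**
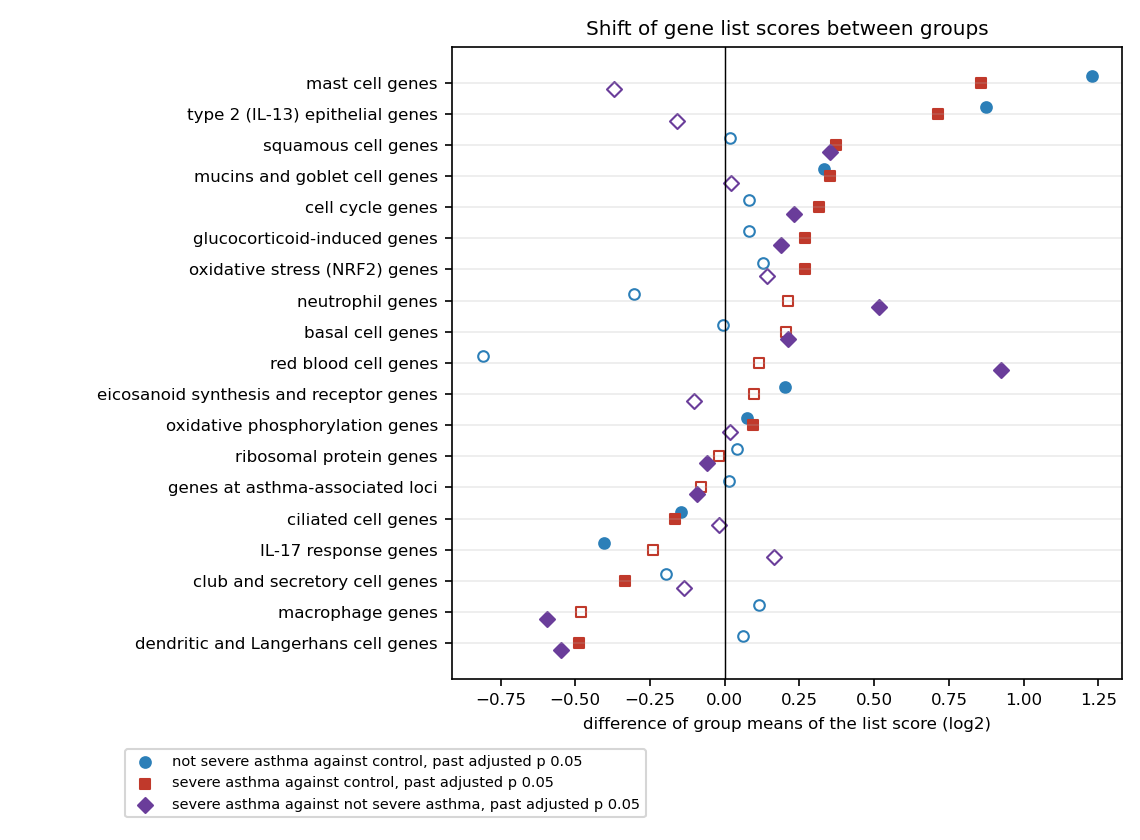
Each symbol is 1 comparison and gene list: the horizontal axis is the difference of the group means of the list score in log2 units, and filled symbols passed an adjusted permutation p of 0.05 while open ones did not. Mast cell and type 2 scores were higher in both asthma groups than in controls (mast cell shifts of 1.23 and 0.86), while the dendritic cell score was lower in severe asthma against both other groups (-0.49 and -0.55).

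The third comparison set severe against not severe asthma. Neutrophil and haemoglobin genes were higher in severe asthma and dendritic cell and macrophage genes lower, while type 2 and mast cell scores gave no shift that passed the permutation test. Against controls, the neutrophil and red blood cell scores of severe asthma shifted by only 0.21 and 0.114 (adjusted permutation p = 0.624 and 0.863). In not severe asthma these 2 scores shifted by -0.305 and -0.809 against controls (adjusted permutation p = 0.294 and 0.0974). DEFA3, a neutrophil defensin whose probe can also read its near-identical neighbour, rose most (1.81 ± 0.39, adjusted p = 0.00112), and SLCO1B3 rose by 1.55 ± 0.25 (adjusted p = 2.45e-05), or by 1.03 and 0.43 with normexp background correction. It was above the median of not severe asthma in 48 of 56 arrays. FCER1A fell to 0.483 of the level in not severe asthma (-1.05 ± 0.17, adjusted p = 2.45e-05), and KCNA1 fell by 1.43 (adjusted p = 0.000122). In all 1290 genes passed, 590 higher and 700 lower, 138 of them by at least 1.5-fold (65 higher and 73 lower).

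Dendritic and Langerhans cell genes fell in 7 of 10 cases, also when adjusted over the list alone. CD1C, which presents lipids to T cells, and CD1E of the same family were at 0.483 and 0.454 of the level in not severe asthma (CD1E at -1.14, or -0.53 by its other probe). CCL17 was at 0.753 of that level. The score fell by 0.55 (permutation p = 1e-05, the smallest possible, and 0.00051 adjusted, camera 6.07e-07, adjusted p = 0.0669 with an estimated correlation). It was lower than the median of not severe asthma in 49 of 56 arrays, with median gene shifts of -0.48, -0.57 and -0.46 within campaigns. Of 14 macrophage genes 5 fell and 9 did not pass (9 fell when adjusted over the list alone): the scavenger receptors MARCO and MSR1 by 1.20 and 0.88, the complement component C1QA by 0.83 and the apolipoprotein APOC1 by 0.98. The macrophage score fell by 0.59 (adjusted permutation p = 0.0353, camera 1.5e-05, adjusted p = 0.525 with an estimated correlation), in campaigns by median gene shifts of -0.88, -0.15 and -0.91. The lipid-handling genes LPL and OLR1, which macrophages also use, fell by 1.24 and 1.26, and C8B, a complement component, by 1.40.

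Of 14 neutrophil genes 5 rose and 9 did not pass, also over the list alone. PROK2, a secreted prokineticin, rose by 1.35 ± 0.32, S100A12, an alarmin of neutrophils, by 1.18 ± 0.32, and the chemokine receptors CXCR1 and CXCR2 by 0.72 ± 0.21 and 0.86 ± 0.25 (0.53 by the other probe of CXCR2). The neutrophil score rose by 0.52 (adjusted permutation p = 0.0282, camera 3.9e-05, adjusted p = 0.504 with an estimated correlation), and within scan days its shift was 0.47 (adjusted p = 0.071). Red blood cell genes moved with it: 4 of 8 rose (5 over the list alone), HBB by 1.21 ± 0.35 and the near-identical HBA1 and HBA2 by 1.44 ± 0.44 and 1.49 ± 0.46. The red blood cell score rose by 0.92 (adjusted permutation p = 0.0151, camera 0.000195, adjusted p = 0.418 with an estimated correlation) or by 0.76 within scan days (adjusted p = 0.0679). Without the 9 doubtful arrays HBA1 (1.35, adjusted p = 0.0564), HBA2 (1.39, adjusted p = 0.0572) and CXCR2 (0.73, adjusted p = 0.0562) no longer passed.

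**Figure D3:**
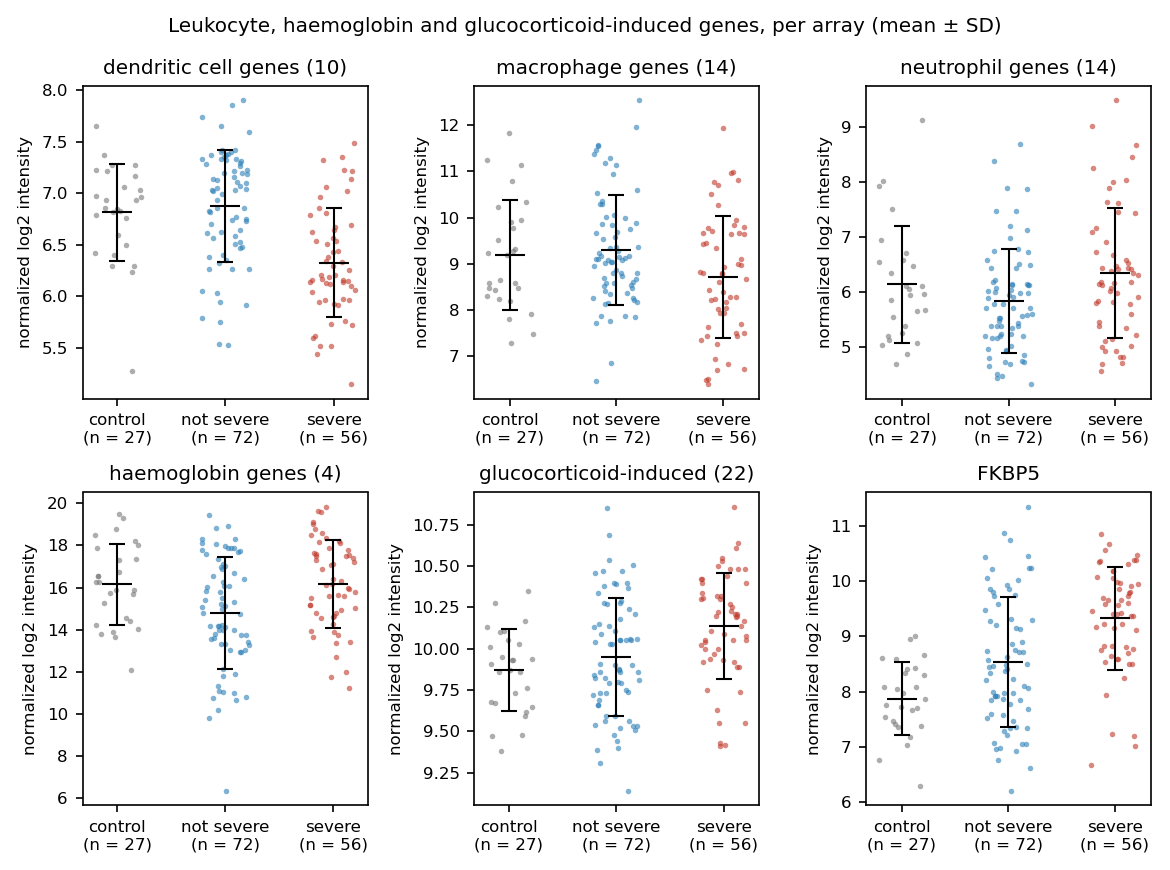
Points are arrays, on a vertical axis of normalized log2 intensity, and bars are the mean ± SD of each group, for the dendritic cell, macrophage, neutrophil, haemoglobin and glucocorticoid-induced scores and for FKBP5. The mean dendritic cell score was 6.82, 6.88 and 6.33 and the mean neutrophil score 6.15, 5.84 and 6.36 in control, not severe and severe asthma arrays.

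Glucocorticoid-induced genes rose in 6 of 22 cases, 8 over the list alone, and none fell. FKBP5 rose 1.73-fold (0.79 ± 0.18, adjusted p = 0.0022), ANGPTL4, an inhibitor of lipoprotein lipase, 1.74-fold, SGK1, a kinase that glucocorticoids induce, 1.37-fold and MAOA 1.18-fold, while TSC22D3 was at 0.28 ± 0.13 (adjusted p = 0.168). The score rose by 0.19 (adjusted permutation p = 0.0151, camera 0.000312, adjusted p = 0.447 with an estimated correlation) and was above the median of not severe asthma in 46 of 56 arrays. Of 21 cell cycle genes 8 rose and none fell (12 over the list alone), with PLK1, a mitotic kinase, at 0.44 ± 0.10, BIRC5 at 0.46 ± 0.13 and CENPF, a kinetochore protein, at 0.24 ± 0.07. The cell cycle score rose by 0.23 (adjusted permutation p = 0.0116, camera 3.98e-08, adjusted p = 0.418 with an estimated correlation).

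Basal cell genes rose in 2 of 15 cases (3 over the list alone), ITGA6, an integrin of the basement membrane attachment, by 0.40 ± 0.09 and S100A2 by 0.37 ± 0.10, while KRT5 was at 0.33 ± 0.14 (adjusted p = 0.129). Their score rose by 0.21 (adjusted permutation p = 0.0181, camera 3.9e-05, adjusted p = 0.418 with an estimated correlation). Of 19 squamous genes 4 rose and 1 fell (6 and 1 over the list alone), KRT6A by 1.10 ± 0.30 and KRT6C by 1.21 ± 0.29 against TGM3 at -0.41 ± 0.11. The squamous score rose by 0.35 (adjusted permutation p = 0.0116, camera 0.000445, adjusted p = 0.418 with an estimated correlation). SCGB1A1 was at 0.64 of the level in not severe asthma (-0.64 ± 0.18, adjusted p = 0.013), among 3 of 16 club cell genes that fell (6 over the list alone). The club cell score was at -0.14 and passed neither test (adjusted permutation p = 0.162, camera 0.0808). Ribosomal protein genes fell by 0.06 in score (adjusted permutation p = 0.044, camera 0.000246, adjusted p = 0.525 with an estimated correlation), with 3 of 28 passing (4 over the list alone), but their median of -0.05 turned to 0.01 after normexp background correction. Of 20 genes at asthma-associated loci IL33, an epithelial alarmin, and RORA, a nuclear receptor, fell by 0.39 and 0.22 (RORA's other probe gave -0.11, and 4 fell over the list alone). The mean score of these loci fell by 0.09 (adjusted permutation p = 0.0498), which camera did not pass (0.35) and whose median gene was at -0.01.

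Type 2 genes differed little between the asthma groups, with a score shift of -0.16 (adjusted permutation p = 0.61) and 2 of 23 members lower, P2RY14 and DPP4 (2 over the list alone). CLCA1 was at -0.56 ± 0.65 (adjusted p = 0.638), POSTN at -0.13 ± 0.27 and NOS2 at 0.08 ± 0.26. Mast cell genes had a median of -0.42 with 0 of 8 past the threshold (camera 0.0245, adjusted permutation p = 0.101, adjusted p = 0.615 with an estimated correlation). Immediate early genes rose in 3 of 19 cases, DUSP1, JUN and CCN2 (6 over the list alone), with a median of 0.29 (camera 1.41e-05, adjusted permutation p = 0.0534, adjusted p = 0.525 with an estimated correlation). Within scan days their score passed (0.32, adjusted p = 0.0422), as did those of oxidative phosphorylation (0.06, adjusted p = 0.0243) and cell junction genes (0.07, adjusted p = 0.0327), of which 1 of 27 and 2 of 22 rose. Eicosanoid genes were at -0.10 in score (adjusted permutation p = 0.107, camera 0.124), with 2 of 20 higher and 4 lower (2 and 5 over the list alone). T and NK cell genes had a median of -0.17, with 1 of 20 lower (camera 0.022, adjusted permutation p = 0.278, adjusted p = 0.698 with an estimated correlation), and IL-17 response genes had a median of 0.15, with 0 of 20 past the threshold (camera 0.0407, adjusted permutation p = 0.202, adjusted p = 0.615 with an estimated correlation). CD86, a costimulatory receptor, was at 1.31 ± 0.44 by the probe used and at -0.63 by its other probe.

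With scan day as a block 684 genes passed, 554 of them among the 1290, and with cell make-up scores as covariates 774, of which 678 were shared. Under the first, SLCO1B3 (1.54), FCER1A (-1.14), FKBP5 (0.93), DEFA3 (1.89) and KCNA1 (-1.25) kept their call and HBA2 (1.36, adjusted p = 0.0962), LPL (-0.95, adjusted p = 0.111) and C1QA (-0.74, adjusted p = 0.0658) did not. Under the second, MARCO (-0.76, adjusted p = 0.107), SCGB1A1 (-0.51, adjusted p = 0.0639) and KRT6A (0.45, adjusted p = 0.234) did not, where MARCO and KRT6A belong to lists that make up these scores, so part of their change was removed by construction. With normexp background correction PROK2 was at 0.40, KCNA1 at -0.61, C8B at -0.40, OLR1 at -0.46 and LPL at -0.52 (adjusted p = 0.101), while HBA2 was at 1.48. The campaigns alone gave 3, 21 and 241 genes, and the count past 1.5-fold was 36 in the authors' value table and 31 with normexp background correction.

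The 2 comparisons against controls used the same 27 arrays, and the last question was how far they moved the same genes. Both moved 474 genes the same way, 283 up and 191 down, and 0 in opposite directions. MUC5B fell in both (-1.25 and -1.23), CLCA1 and CPA3 rose in both, and FKBP5 (0.66 and 1.45) and SCGB1A1 (-0.61 and -1.26) passed only in severe asthma, each with a difference between the asthma groups that passed as well, although SCGB1A1 passed in both with normexp background correction and then not between the asthma groups. Independent lists of these sizes would share 28.8 and 22.8 genes. In 20 simulations with resampled arrays and no changed gene, limma gave at most 0 shared genes. Few genes can pass either comparison when none is changed, so this cannot show how far shared controls raise the count. With the controls split at random into 2 parts the shared count had a median of 3.5 (range 0 to 35 in 20 splits). Each comparison then had fewer controls, so fewer genes could pass. The drop from 474 can therefore not be put down to shared controls alone. Across all genes, which are not independent replicates, the fold changes correlated at r = 0.716, which lay inside the range of 0.373 to 0.852 (mean 0.652) of 100 simulations of unchanged groups. It compares with a median of 0.464 (0.292 to 0.615) over 100 splits of the controls. The covariance was 0.0347, against 0.00946 simulated and 0.0264 with split controls. With scan day as a block the shared genes numbered 135, with cell make-up scores 110 and with array quality weights 1087. An F-test over the 3 groups gave 2747 genes.

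**Figure D4:**
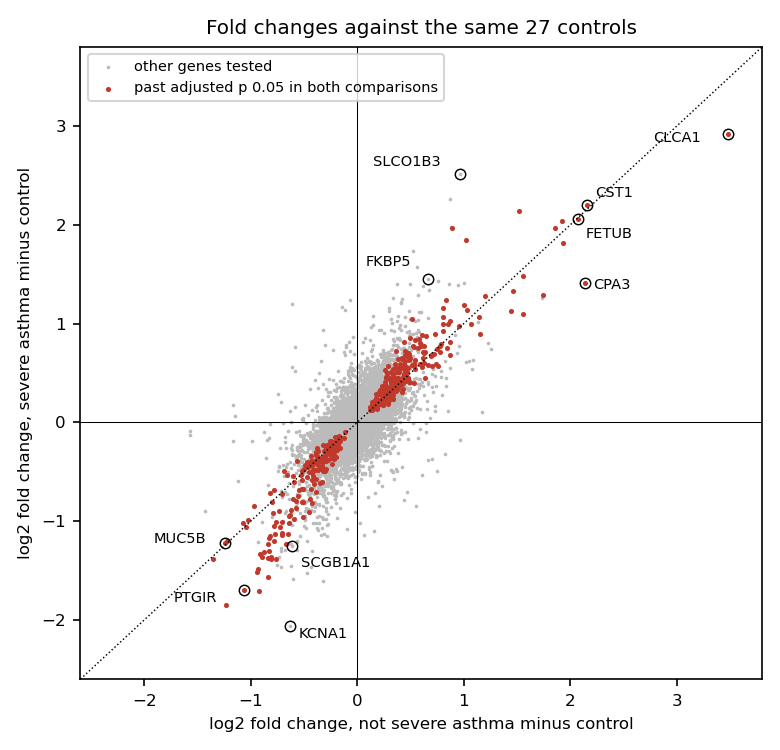
Each point is 1 of 15633 genes, with the log2 fold change of not severe asthma against control on the horizontal axis and of severe asthma against control on the vertical axis; red points passed an adjusted p of 0.05 in both, and the dotted line marks equal changes. CLCA1 lies at 3.48 and 2.92, and SLCO1B3 and KCNA1 lie far from 0 on the vertical axis at 2.52 and -2.06.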

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

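Differences between the 2 asthma groups were tested directly by permuting array labels for the lists and with limma for single genes; the tests of epithelial share, of scan day and cell make-up for FKBP5, and of leukocytes in general were chosen after the result was seen, as were the label permutation of list scores and the splits within scan days. Relative to not severe asthma, severe asthma had mean shifts of 0.211 in basal, 0.353 in squamous, 0.515 in neutrophil, -0.594 in macrophage, -0.549 in dendritic, 0.923 in red blood cell, 0.187 in glucocorticoid-induced and 0.233 in cell cycle genes, of -0.061 in ribosomal protein genes (whose median turned to 0.014 after normexp) and of -0.093 in genes at asthma loci. FKBP5 differed by 0.79 and SCGB1A1 by -0.64. Each drew attention because severity groups differ under the same contrast with the controls. Probes with no matched gene, which the comparisons did not use, passed in 739, 616 and 456 cases of 10629 in the 3 comparisons.

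Neutrophil genes rose while macrophage and dendritic cell genes fell in severe against not severe asthma. A different share of epithelial cells stays open for the falls: the mean of the T and NK, B and plasma, mast and eosinophil scores was at -0.139 ± 0.0751 (permutation p = 0.069), which decides neither way. The neutrophil minus macrophage score differed by 1.15 ± 0.26 within scan days (permutation p = 2e-05), but this difference joins the rise and the fall. Taken alone within scan days, the macrophage and dendritic cell scores shifted by -0.675 and -0.571 (adjusted permutation p = 0.0333 and 0.00051). This argues against scanning batch for the falls. The neutrophil score shifted by 0.474 within scan days (adjusted permutation p = 0.071), against 0.515 without, which leaves scanning batch undecided for the neutrophil rise. With the haemoglobin score as covariate the neutrophil shift went from 0.515 to 0.182 ± 0.162 (permutation p = 0.25), so blood in the brushings may account for much of the neutrophil part. Severity itself was not tested against these as an explanation.

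Glucocorticoid-induced genes rose in severe against not severe asthma. With scan day as a block FKBP5 was at 0.93 (adjusted p = 0.00134) and with cell make-up scores at 0.67 (adjusted p = 0.0137), against 0.79 without. This argues against scanning batch for that gene, and against the ciliated and squamous make-up and the pooled amount of leukocytes that those scores follow. The leukocyte score pooled lists that moved in opposite directions here (neutrophil 0.515, macrophage -0.594 and dendritic -0.549). It cannot follow a shift among kinds of leukocytes, which stays open. Basal and club cell scores were not covariates, so a change in those cells stays open. A difference in medication is a candidate explanation that the labels do not allow to be tested, beside severity.

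Mast cell genes rose in not severe asthma against controls. More leukocytes of all kinds would move the other leukocyte scores as well. The mast cell score rose beyond the mean of the T and NK, macrophage and neutrophil scores by 1.26 ± 0.261 (permutation p = 3e-05). The eosinophil score was not in that mean and was higher by 0.328 (adjusted permutation p = 0.0534), so a rise shared with eosinophils was not tested. Within scan days the mast cell score rose by 1.4 ± 0.276 (permutation p = 1e-05, the smallest these permutations can give), which argues against scanning batch. That mast cells were more numerous may be the reason, or that each held more of these transcripts, and the arrays do not separate the 2.

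Random splits of the arrays tell whether chance can be excluded. For the gene counts it can under free splits, which do not keep the scan days: only the real split among 100 (1 of 100) reached 859 genes in not severe asthma against control (highest other 380), 1872 in severe asthma against control with missing values filled (highest other 71), 1290 between the asthma groups (highest other 24) and 2747 in the F-test (highest other 6). The same held past 1.5-fold, with 137, 456 and 138 genes against 10, 4 and 1. It also held for splits within scan days with the day as a block, where the real split (1 of 100 each time) gave 162, 2064 (missing values filled) and 684 genes and the highest others 4, 24 and 134. For the camera list counts chance cannot be excluded, since 34, 7 and 15 of 100 splits gave as many as 11, 15 and 13 lists, with highest others of 18, 16 and 17.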

How the results depend on the processing

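Fits within single campaigns, campaign as a block and the label permutations were added after seeing the data. Over 14 settings, the 39 list calls by camera at the preset correlation kept direction and threshold in 490 of 546 values, lost the threshold in 54 and reversed in 2. These settings leave out the estimated correlation, with which 0 lists passed. The tally is of camera calls, not of the 7, 11 and 10 lists that passed the label permutation. Over 16 settings the 226 named gene calls kept both in 3174 of 3607 values, lost the threshold in 432 and reversed in 1. Within single campaigns, where fewer arrays limit the tests, 75 of 117 list values and 61 of 678 gene values kept both, 36 and 614 were weaker, and 6 and 3 reversed. Apart from the values below, the gene counts in other settings were 718 to 978, 1629 to 2792 and 927 to 1543 against 859, 1871 and 1290, the F-test 2069 to 3525 against 2747, and r 0.7021 to 0.7431 against 0.7159. Arrays with 41.78% to 97.47% of probes above background limit calls on dim genes. Slide as a random block gave no list values, since camera takes no block.

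The cause was not tested for any change given here, except that single campaigns hold fewer arrays. In the order not severe asthma against control, severe asthma against control, severe against not severe asthma, genes past 1.5-fold (137, 456, 138) numbered 54, 124 and 31 with normexp background and 50, 1.6e+02 (rounded) and 36 in the authors' value table. With array quality weights 1799 genes passed in the first comparison and 1087 were shared by the comparisons against control (474). Scan day as a block left 162 genes in the first and 684 in the last, 56 past 1.5-fold in the first and 135 shared. Cell make-up scores left 187, 796 and 774 genes, 60 and 256 past 1.5-fold in the first 2 comparisons, 1337 in the F-test and 110 shared. By camera with an estimated inter-gene correlation 0, 0 and 0 lists passed (4, 3 and 2 at an unadjusted p under 0.05), by fry 6 and 9 in the first 2 comparisons, and by label permutation of list scores 7 in the first.

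Campaign 1 alone gave 0, 9 and 3 genes by limma (722, 1671 and 1899 at an unadjusted p under 0.05), 0, 9 and 2 past 1.5-fold, 3 in the F-test, 7 lists in the last comparison and 0 shared genes. The 722 are no more than unchanged genes alone would give on average. Campaign 2 alone gave 66, 648 and 21 genes, 29, 268 and 10 past 1.5-fold, 432 in the F-test, 7 lists in the first comparison, r = 0.7737 and 32 shared genes. Campaign 3 alone gave 0, 0 and 241 genes by limma (2478, 1330 and 2979 at an unadjusted p under 0.05), 0, 0 and 71 past 1.5-fold, 211 in the F-test, r = 0.574 and 0 shared genes. For the first comparison it held 7 controls and 23 asthma arrays, against 6 and 20 in campaign 1. The number of arrays alone therefore leaves the gap between 2478 and 722 open.

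Reversed values, by the direction of the test and with cause not tested, were these. With normexp background, the median of ribosomal protein genes in not severe asthma against control (-0.186) and in severe against not severe asthma (0.014), and RPS23 in not severe asthma against control (-0.05). In campaign 1 alone, SMAD3 in severe asthma against control (0.05). In campaign 2 alone, in not severe asthma against control, the medians of neutrophil (0.117), oxidative phosphorylation (-0.001) and ribosomal protein genes (-0.002). In campaign 3 alone, immediate early genes (0.124) and NR4A3 (0.01) in not severe asthma against control, and COX5A in severe against not severe asthma (-0.01). There the direction given by camera also turned for IL-17 response genes in severe asthma against control (median -0.033) and mast cell genes in severe against not severe asthma (median -0.002), while the medians kept their sign near 0.

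The replicate block, which treats the numbers in the titles as pairs, gave 1446 and 377 genes in the first and last comparisons, 258 and 58 past 1.5-fold, r = 0.8173 and 898 shared genes. The numbers count biological replicates within each group. In the pairing check 2 of 27, 3 of 27 and 17 of 56 pairs correlated above 0.1, with means of -0.0828, -0.0273 and 0.0309.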

Other observations

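Of the tests in this part, the label permutation of list scores, also within scan days, was chosen after results had been seen. Lists that passed neither camera nor the label permutation over all arrays in any comparison had few members past the threshold. Of 18 unfolded protein response genes 1 rose in not severe and 2 in severe asthma against control, SDF2L1, an endoplasmic reticulum protein, in both (0.32 ± 0.08 and 0.44 ± 0.08), with camera at 0.0846 and 0.084, and 1 fell between the asthma groups (SEL1L, -0.26 ± 0.09, camera 0.713). Of 13 rare epithelial cell genes 1 fell in not severe asthma (AVIL, -0.51 ± 0.14, or -0.25 by its other probe, camera 0.595). In severe asthma against control 1 rose, ASCL3 of ionocytes (1.11 ± 0.21), and 2 fell, among them GRP (-0.98 ± 0.31, camera 0.391), and between the asthma groups ASCL3 and AVIL rose (0.54 ± 0.16 and 0.36 ± 0.11, or 0.10 by the other probe of AVIL, camera 0.595). Of 22 cell junction genes 1 fell in not severe asthma (CTNND1, -0.18 ± 0.06, but 0.09, 0.07 and 0.01 by its other probes, camera 0.222). PKP2, a desmosomal protein, and MARVELD3 rose in severe asthma (0.47 ± 0.10 and 0.23 ± 0.07, or 0.07 by the other probe of MARVELD3) and CGN fell (-0.26 ± 0.09, camera 0.683). Between the asthma groups PKP2 and DSG3 rose (0.23 ± 0.08 and 0.72 ± 0.21, camera 0.394), where the score passed within scan days only (0.074, adjusted p = 0.0327). Of 20 matrix genes CHI3L1 fell against controls in both (-0.82 ± 0.23 and -0.71 ± 0.24), while SNAI2, LOX and TGFB2 rose in severe asthma against control (0.46 ± 0.14, 0.31 ± 0.10 and 0.49 ± 0.17), and between the asthma groups MMP7 rose (0.63 ± 0.19), with camera at 0.926, 0.899 and 0.816. Of 28 interferon-stimulated genes RSAD2 and IFIT1 fell in severe asthma against control (-0.47 ± 0.13 and -0.54 ± 0.16, camera 0.1), and camera gave 0.436 and 0.2 in the other comparisons.

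Further lists gave camera values, in the order not severe against control, severe against control and severe against not severe, of 0.202, 0.428 and 0.713 for 7 eosinophil genes, 0.337, 0.721 and 0.5 for 8 B and plasma cell genes, 0.114, 0.43 and 0.482 for 13 cyclic AMP-induced genes, 0.608, 0.249 and 0.337 for 17 interferon-gamma response genes, 0.6, 0.808 and 0.35 for 17 heat shock genes, 0.899, 0.446 and 0.227 for 7 aryl hydrocarbon receptor genes, and 0.71, 0.807 and 0.891 for 12 fibroblast, smooth muscle and endothelial genes. HLA-DRA, an antigen-presenting molecule, fell between the asthma groups (-0.39 ± 0.12), and NR4A2 in not severe asthma against control (-0.43 ± 0.13). Of 20 genes at asthma-associated loci 2 rose in not severe asthma against control, and 2 rose and 4 fell in severe asthma against control (camera 0.782 and 0.373).

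Relations between scores were tested within groups by permutation, adjusted over 12 relations. The mast cell and type 2 scores correlated at r = 0.636 in controls (rho = 0.679, permutation p = 0.00031, adjusted p = 0.00053, r = 0.564 without the 2 farthest arrays, and 0.507, 0.822 and 0.573 within campaigns). It was 0.762 in not severe asthma (rho = 0.787, permutation p = 1e-05, the smallest possible, adjusted p = 3e-05, r = 0.753 without 2, and 0.83, 0.759 and 0.748) and 0.645 in severe asthma (rho = 0.694, permutation p = 1e-05, adjusted p = 3e-05, r = 0.651 without 2, and 0.644, 0.68 and 0.628). The glucocorticoid-induced and dendritic cell scores gave r = 0.296 in controls (rho = 0.303, permutation p = 0.13, adjusted p = 0.14, r = 0.449 without 2, and 0.425, 0.0972 and 0.398). They gave -0.551 in not severe asthma (rho = -0.533, permutation p = 1e-05, adjusted p = 3e-05, r = -0.508 without 2, and -0.543, -0.765 and -0.335) and -0.4 in severe asthma (rho = -0.35, permutation p = 0.0023, adjusted p = 0.0034, r = -0.361 without 2, and -0.416, -0.327 and -0.824).

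The squamous and ciliated scores gave r = 0.115 in controls (rho = -0.0354, permutation p = 0.56, adjusted p = 0.56, r = -0.21 without 2, and 0.553, -0.35 and 0.0456 within campaigns). They gave -0.259 in not severe asthma (rho = -0.272, permutation p = 0.027, adjusted p = 0.032, r = -0.292 without 2, and -0.0548, -0.164 and -0.57) and -0.354 in severe asthma (rho = -0.35, permutation p = 0.0074, adjusted p = 0.0099, r = -0.399 without 2, and -0.247, -0.438 and -0.466). The neutrophil and haemoglobin scores gave r = 0.646 in controls (rho = 0.589, permutation p = 3e-04, adjusted p = 0.00053, r = 0.558 without 2, and 0.953, 0.65 and 0.642). They gave 0.603 in not severe asthma (rho = 0.599, permutation p = 1e-05, adjusted p = 3e-05, r = 0.565 without 2, and 0.56, 0.564 and 0.686) and 0.536 in severe asthma (rho = 0.585, permutation p = 3e-05, adjusted p = 7.2e-05, r = 0.639 without 2, and 0.373, 0.537 and 0.689).

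The type 2 score varied more between arrays in asthma, with SDs of 1.07 and 1.15 in the 2 asthma groups against 0.68 in controls, a difference of 0.44 (permutation p = 0.0032). Correlations of genes with FKBP5 within the arrays of not severe asthma went weakly with their differences in severe against not severe asthma, at r = 0.28 across genes. This was percentile 97.6 among 1000 random genes (median -0.0148, 95th percentile 0.223), but percentile 93.1 by size regardless of sign. FKBP5 itself differed between the asthma groups (0.79), while the other genes were taken at random. The rank therefore does not show a link particular to FKBP5.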
